A study of Mus musculus with 6 samples.

How the data were processed

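The series holds 6 samples of projection neuron cell bodies purified from mice at postnatal day 1. Callosal projection neurons (CPN), marked as controls in the labels, gave 3 samples, and subcerebral projection neurons (SCPN) gave another 3. Per the labels' protocols, microRNA was isolated with the miRVana kit, and per the series' design text it was run on TaqMan Low Density Array rodent microRNA cards, whose content follows miRBase release 10. Each well of such a card is a separate quantitative PCR for 1 microRNA, and its threshold cycle (Ct) is the cycle at which fluorescence crosses a set level, so a lower Ct means more template. How neurons were labelled and sorted, whether the cDNA was amplified beforehand, and how thresholds were set are not given in the sources used here. The labels do not say whether samples of a group came from separate animals or litters. The p-values thus measure the spread between these samples, which may be technical, except where a test takes assays as its observations, as given below.

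The deposited raw sheet gives a Ct, or no call, for 768 wells on 2 cards (A and B). Of these, 734 wells hold 584 microRNA assays, 375 on card A and 209 on card B, and 150 assays have 2 wells. Names mark 517 assays as mouse and 67 as rat. The remaining wells are 32 endogenous control wells and 2 wells of a plant assay, which gave a Ct in 0 wells. The deposited normalised sheet was compared with the raw one: the authors had subtracted from each Ct the geometric mean of the control Ct of the same sample and card, over 8 wells on card A and over the means of 6 control assays on card B. The authors' deposited fold table gives a ratio, the relative quantity (RQ), for 240 assays with a Ct in all 6 samples. It equals 2 raised to the mean normalised Ct of CPN minus that of SCPN, so that a ratio above 1 means more in SCPN. In all 6 samples the wells of a duplicated assay stand in ascending order of Ct, so well identity was not kept. The median gap between such wells was 0.0978 to 0.154 cycles where Ct was under 30.

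Values were computed from the raw Ct. Wells of 1 assay were averaged over those with a Ct, so an undetermined well beside a determined one was left out. This was so for 2 to 13 duplicated assays per sample, whose level may be read too high. An assay mean of 35 or more, or an assay with no Ct, was set to 35. The mean Ct of the microRNA assays with Ct under 35 in all 6 samples was then subtracted per sample and card (159 assays on card A, 65 on card B). The sign was turned so that a higher value means more template, and 1 unit is 1 cycle, or a log2 unit at full PCR efficiency. Levels below are on this scale, where 0 is the mean of the commonly detected assays of the card. Assays with Ct under 35 in at least 3 of the 6 samples were tested, which left 306 (208 on card A and 98 on card B), while 211 assays were detected in 0 samples and 67 in 1 or 2. Differences are SCPN minus CPN, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An assay at the limit has only a bound, so a difference against a group at the limit is a lower bound. No read depth exists for such data. The precision rests on the 3 samples per group and, for low assays, on the Ct limit.

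Lists of microRNAs were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, adjusted over the 17 of 23 lists that met this. Camera with an estimated correlation, camera on ranks and fry were run beside it. The lists are the imprinted 12qF1 (Dlk1-Dio3) microRNAs, the miR-193b/miR-365 pair, markers of neurons, neuronal activity, astrocytes, oligodendrocytes, microglia and blood, erythroid cells, vascular cells and muscle, the progenitor-associated miR-17/miR-92 group with its paralogs, the let-7, miR-30, miR-181, miR-29, miR-15/miR-16, miR-34/miR-449, miR-99/miR-100/miR-125 and miR-200/miR-183 families, the Hox-linked miR-10/miR-196 group, the embryonic stem cell miR-290/miR-302 group, the Sfmbt2 group and the minor strands (names ending in an asterisk). Minor strand is used here for the name alone, which need not mark the less abundant strand. The groups, the tests, the lists, the alternatives and the rule for naming assays were fixed before the data were examined. The 12qF1 and miR-193b/miR-365 lists were written with knowledge that the study had singled out these clusters from these samples, so their direction is not independent evidence. Per-sample values were compared with exact permutation tests, which cannot go below 0.1 with 3 against 3. Neighbouring microRNA genes were found by name in a gene table of assembly GRCm38.p6, used for names and neighbourhood alone, and joined where they lay within 10 kb. Of the 584 assays, 499 matched 1 gene, 49 matched several copies and 36 matched none.

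By the naming rule the text names the 10 assays with the smallest unadjusted p in each direction where fewer than 10 pass the adjusted threshold, both miR-193b/miR-365 assays, for the 12qF1 list the 4 members with the smallest p and the 4 most abundant, for other lists the 3 most abundant and the 2 with the smallest p, the 10 largest deposited ratios in each direction, the control assays, and any assay detected in every sample of 1 group and in none of the other. The rule gives 94 assays. All of them were carried through every alternative in which they could be tested, and the text of the report names those that illustrate a group. Outside the rule, miR-124, miR-218, miR-218-1*, miR-376b and the mouse-named assay for miR-136* were named after their values were seen. They were not carried through the alternatives.

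Replicate numbers come from the titles and descriptions. Deviations from the group means correlated at 0.70, 0.33 and 0.28 between samples with the same number, across assays, so the numbers were taken to pair the samples. SCPN replicate 3 correlated more with CPN replicate 2 (0.41), and SCPN replicate 2 with CPN replicate 3 at 0.26. Only the samples numbered 1 thus stand out as a pair. The labels do not state a pairing, and the pair and block results below rest on this choice. The fit with the replicate number as a block is given where it changes a call or a count. No pair of samples held identical values. The procedure was tested on simulated data with the spread of these samples over 306 assays. It recovered 27.7% of assays changed by 2 log2 units, 90.6% of those changed by 4 and 98.1% of those changed by 6, with 3.17% false among the calls, and camera called a simulated 12qF1 shift of 1.5 in 100% of 50 runs. The simulated errors were independent between assays, and no value was held at the Ct limit. In the real data the estimated correlation within a list was 0.014 for 12qF1 but 0.87 for miR-181. The simulated shares may therefore not hold for the real data. Other tools were Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives covered the scaling, the detection limit, the filter, the handling of missing values, the moderation, sample weights, the replicate block, each sample left out in turn, mouse-named assays alone, and the form of the list test. Alternatives added after seeing the data were the deposited scaling without U6, leaving out both samples numbered 1, each card alone, and the 12qF1 list restricted to mouse-named assays with Ct under 30 in all 6 samples.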

Results

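MicroRNA levels were measured by quantitative PCR in 3 samples of callosal and 3 samples of subcerebral projection neurons of the newborn mouse cortex. Callosal neurons connect the hemispheres, and subcerebral neurons, which include the corticospinal neurons, send axons to the brainstem and spinal cord. CPN samples detected 319, 250 and 319 assays with Ct under 35, and SCPN samples 331, 278 and 265. The means were 296 ± 39.84 (SD, n = 3) in CPN and 291 ± 34.96 (SD, n = 3) in SCPN, and the exact two-sided permutation p was 1.0, where 0.1 is the smallest possible. The mean Ct of commonly detected card A assays ran from 21.8 in SCPN replicate 1 and 22.6 in CPN replicate 1 to 27.1 and 27.2 in SCPN replicates 2 and 3 and 28.1 in CPN replicate 2, with CPN replicate 3 at 24.7. The group means differed by 0.246 cycles on card A, where the SD within groups was 2.76 in CPN and 3.12 in SCPN, and by 0.187 on card B.

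**Figure D1:**
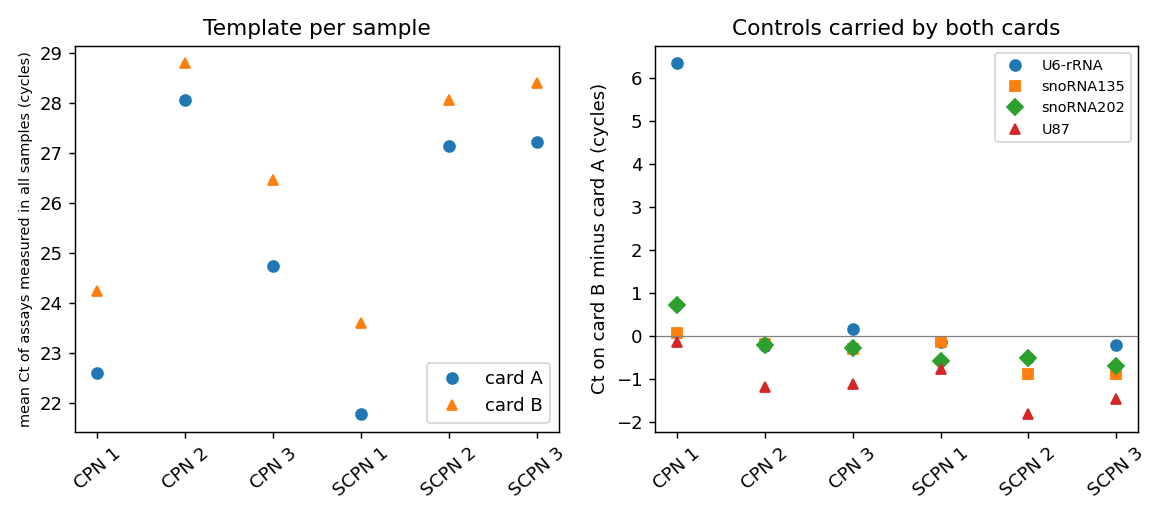
Left, mean Ct in cycles of the microRNA assays measured in all 6 samples, per sample and card; both samples numbered 1 have the lowest Ct. Right, Ct on card B minus Ct on card A in cycles for 4 of the controls carried by both cards (Y1 is not drawn); U6 in CPN replicate 1 lies at 6.33, against -0.51 to 0.16 in the other 5 samples.

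The comparison of SCPN with CPN asked which microRNAs differ in level between these classes of cortical neuron. MicroRNAs of the imprinted 12qF1 (Dlk1-Dio3) region, a large maternally expressed cluster, were higher in SCPN as a group. Of 43 members tested, 42 had a higher mean in SCPN and 1 a lower mean, with a median log2 difference of 1.56 (mean 1.75, SD over members 1.00), against -0.27 for the other 263 assays. The 32 members measured in every sample are among the assays whose mean sets the scale. A rise in these members by itself lowers the other assays on that scale, so the -0.27 does not show that the others fell. Among the most abundant members on the scale set per card, miR-434-3p stood at 3.04 ± 0.48 in CPN and 4.20 ± 0.65 in SCPN, miR-127 at 2.99 ± 0.56 and 4.04 ± 0.38, miR-409-3p at 1.86 ± 0.83 and 3.43 ± 0.89, and miR-485*, on card B, at 2.92 ± 0.22 and 3.83 ± 0.38 (log2 level, SD, n = 3 each). The median level of the 32 members measured in every sample, minus that of the other assays, was -2.005, -2.03 and -1.39 in CPN and 0.13, 0.22 and 0.25 in SCPN.

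Camera gave the 12qF1 list an adjusted p of 2.31e-23, and an adjusted p of 0.00763 with an estimated correlation. That estimate, 0.014, was close to the preset 0.01, so the correlation does not account for the gap between these p. The preset form takes the assays as its observations, so its p does not measure the spread between samples. The form with an estimated correlation is limited by the number of samples. The fry p was 0.000722 for a shift in 1 direction. Per sample the list differed by 2.01 log2 units, with an exact permutation p of 0.1, the smallest possible. The 3 same-numbered pairs differed by 2.13, 2.25 and 1.64. As every SCPN sample lay above every CPN sample, any pairing would agree in direction, so this adds no support. The same exact p was reached, with lower levels in SCPN, by miR-17/miR-92 (-1.02), miR-181 (-1.34), miR-15/miR-16 (-0.88), miR-34/miR-449 (-0.79) and miR-99/miR-100/miR-125 (-1.22). After adjustment over the lists this exact permutation p was 0.27 for each of them and for 12qF1. In 33 of the 43 12qF1 members SCPN exceeded CPN in all 3 pairs. No member passed when adjusted over all assays, and 1 member, miR-666-5p, passed when adjusted over the list alone, a count that was 18 with the replicate block, 2 without CPN replicate 2, and 0 without CPN replicate 1 or any 1 of the SCPN replicates. It was also 0 with median scaling, quantile normalization, a limit of Ct 32 or no limit, 2 with either planned scaling on controls or with assays detected in all 6 samples, 3 with trend and robust moderation and 8 with sample weights. Groups did not overlap in 19 members, all higher in SCPN (44.2%, against 15.03% of all tested assays and 10% by chance). As the study singled out this cluster from these samples, the direction is not independent evidence.

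**Figure D2:**
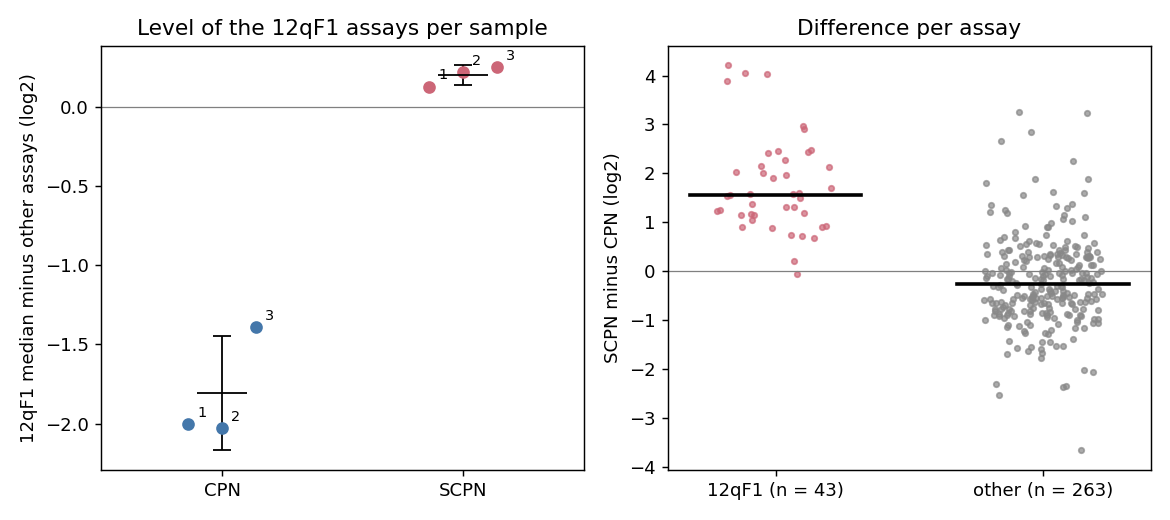
Left, median log2 level of the 12qF1 assays minus that of the other assays in each sample (points, numbered by replicate), with group mean and SD bars; the CPN samples lie between -2.03 and -1.39 and the SCPN samples between 0.13 and 0.25. Right, SCPN minus CPN log2 difference of each tested assay, with black lines at the medians, 1.56 for 43 12qF1 assays and -0.27 for 263 other assays.

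The 4 largest 12qF1 differences were those of miR-485, the rat-named assay for miR-136*, miR-376b* and miR-666-5p. MiR-666-5p had the smallest p of all assays, at a log2 difference of 3.89 ± 0.70 (SE), and its levels were -6.88 ± 1.13 in CPN and -2.99 ± 0.13 in SCPN (SD, n = 3 each). MiR-376b* stood at -0.82 ± 1.37 in CPN and 3.21 ± 3.30 in SCPN (SD, n = 3 each), and its difference was 2.12 without SCPN replicate 2. The rat-named assay for miR-136* differed by 4.05 ± 0.98, miR-485 by 4.21 ± 1.26, miR-376b* by 4.03 ± 1.60 and, among the smallest p, miR-376a* by 2.47 ± 0.63, miR-376a by 2.27 ± 0.58, miR-136 by 2.42 ± 0.74 and miR-379 by 1.89 ± 0.59 (SE). MiR-485 was detected in 1 CPN sample and in all 3 SCPN samples, so its difference depends on the Ct limit. The mouse-named assay for miR-136* differed by 1.37 ± 1.19 (SE), detected in 1 CPN and 2 SCPN samples. The other strands of miR-485 and miR-376b* differed less, miR-485* by 0.91 ± 0.54 and miR-376b by 1.25 ± 0.78 (SE). The size of a difference thus varied between assays of the same gene, while miR-376a and miR-376a* were close. Both gene neighbourhoods of the region were higher in SCPN, the Mir379 to Mir410 genes by a median of 1.57 over 29 assays (camera adjusted p 1.04e-14) and the Mir770 to Mir136 genes by 1.49 over 13 assays (adjusted p 1.08e-06). With an estimated correlation their adjusted p were 0.0242 and 0.0415.

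The miR-193b/miR-365 pair, processed from neighbouring genes, had nearly the same difference in both members. MiR-193b stood at 3.77 ± 0.51 in CPN and 5.66 ± 0.25 in SCPN, and miR-365 at -2.84 ± 0.42 and -0.95 ± 0.60 (SD, n = 3 each). The log2 differences were 1.89 ± 0.56 and 1.89 ± 0.60 (SE), 3.72-fold and 3.71-fold, in the same direction in all 3 pairs. The groups did not overlap in either assay, so the pairs could only agree. The limma adjusted p over all assays was 0.40 for each, and 2 of 2 passed when adjusted over the list alone. That count was 0 without SCPN replicate 2 and 0 without SCPN replicate 3, and the study chose this pair on these samples, so it is not independent evidence.

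Over all 306 assays, 0 passed adjusted p 0.05 by limma, and the smallest adjusted p was 0.21. At an unadjusted p under 0.05 there were 25 assays, where 15.3 are expected by chance, with 20 higher in SCPN, 14 of them from 12qF1, and 5 lower. With the replicate block 51 assays had such a p and again 0 passed after adjustment, and with sample weights 42 did and 1, miR-666-5p, passed at adjusted p 0.029 (0.029 to 0.57 over its alternatives). Without SCPN replicate 3 the count at unadjusted p under 0.05 was 14. Among assays outside 12qF1 with the smallest p, miR-700 differed by 2.26 ± 0.71 (SE). Detected in all SCPN samples and in 0 CPN samples was miR-218-2*, from a gene family known from motor neurons. With CPN taken at the Ct limit, its mean was 9.50-fold higher in SCPN, which bounds the means of these samples alone. The limit differed between samples on this scale, and SCPN replicate 1, at -7.41, lay below the limit of CPN replicate 2, at -6.20. The log2 difference of miR-218-2*, 3.25 ± 1.37 (SE, limma adjusted p 0.58), was 2.12 without CPN replicate 1 and 4.32 without CPN replicate 2. Without any 1 of the SCPN replicates it was detected too rarely to be tested. The other tested assays of this family differed less, miR-218 by 0.91 ± 1.03 and miR-218-1* by 0.030 ± 0.88 (SE).

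Lower values in SCPN were led by miR-133a, a muscle microRNA also found in brain, at -2.03 ± 0.23 in CPN and -5.70 ± 1.30 in SCPN (SD, n = 3 each), a log2 difference of -3.67 ± 0.76 (SE) with a limma adjusted p of 0.24. The other muscle assay tested, miR-206, detected in 2 CPN and 3 SCPN samples, differed by 2.85 ± 1.05 (1.80 without CPN replicate 1), so the muscle list went both ways, and 2 of its 2 members passed when adjusted over the list alone. That count was 1 without CPN replicate 1, CPN replicate 2, SCPN replicate 2 or both samples numbered 1, 1 with scaling on controls, a limit of Ct 32 or sample weights, and 4 of 4 tested with no limit and no filter. MiR-501-3p differed by -2.32 ± 0.75, miR-652 by -2.36 ± 0.99 (-1.56 without SCPN replicate 1), miR-92a by -2.02 ± 0.72, miR-210, a hypoxia-responsive microRNA, by -1.70 ± 0.84, miR-671-3p by -1.60 ± 0.64, miR-181a by -1.58 ± 0.70, miR-152 by -1.56 ± 0.73 (-0.92 without CPN replicate 1), miR-296-5p by -1.54 ± 0.73 and miR-342-5p by -1.45 ± 0.65 (SE). None of these passed after adjustment, and each was lower in all 3 pairs, which choosing assays by small p favours.

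**Figure D3:**
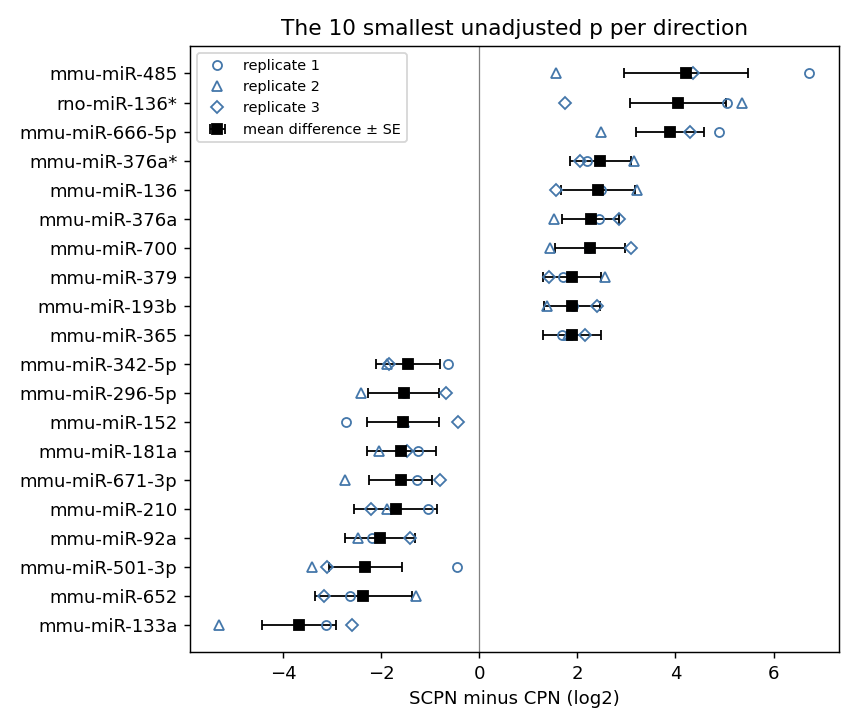
SCPN minus CPN log2 difference of the 10 assays with the smallest unadjusted p in each direction (black squares, mean with SE bars) and the difference within each pair of equal replicate number (open symbols). All pair differences of these 20 assays lie on the side of their mean, from -3.67 for miR-133a to 4.21 for miR-485 as means, and none passed adjusted p 0.05. Choosing assays by small p favours such agreement between pairs.

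The miR-17/miR-92 group and its paralogs, known for driving proliferation of progenitors, had 13 of 16 members lower and 3 higher in SCPN, with a median log2 difference of -0.57. Its abundant members varied: miR-17 differed by -0.49 ± 0.54, miR-106a by -0.58 ± 0.54 and miR-19b by 0.02 ± 0.55, beside miR-92a and miR-18a* at -0.96 ± 0.56 (SE). Camera gave an adjusted p of 0.0446, and an adjusted p of 0.61 with an estimated correlation, and 0 members passed over the list alone. The call was also lost without CPN replicate 1 (adjusted p 0.53), CPN replicate 3 (0.20), SCPN replicate 2 (0.13) or SCPN replicate 3 (0.11), and it held in 8 of 24 alternatives. Scaling on control assays turned the sign of miR-17 and miR-106a, though the list stayed below the other assays.

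None of the other 15 lists tested passed adjusted p 0.05 with the scaling used here. The 3 miR-181 assays were all lower in SCPN, with a median of -1.003 (camera adjusted p 0.13), and 1 of them, miR-181a, passed over the list alone with the replicate block, against 0 without it. The miR-99/miR-100/miR-125 family had 9 of 11 members lower, led by the abundant miR-125b-5p at -1.11, with a median of -0.79 (adjusted p 0.15). Its level per sample relative to the other assays differed by -1.22, with pairs at -0.24, -2.24 and -1.18. The miR-30 family had 8 of 8 lower with a median of -0.48 (adjusted p 0.25), and without SCPN replicate 1 the miR-30 and miR-181 lists each had an adjusted p of 0.048, which was 0.65 with an estimated correlation. Relative to the other assays the miR-30 list lay at -0.43 with all samples, at -0.73 without SCPN replicate 1 and at -0.041 without CPN replicate 1. Medians were -0.64 for the miR-34/miR-449 family with 5 of 5 lower (adjusted p 0.32), -0.62 for miR-15/miR-16 with 8 of 9 lower (0.35) and -0.29 for miR-29 with 4 of 5 lower (0.44). The let-7 family had 5 higher and 6 lower, with a median of -0.0039, a mean of 0.08 and an upward test at adjusted p 0.94. The Sfmbt2 group had 4 of 6 lower with a median of -0.08 (0.74), and the 64 minor strand assays split into 32 higher and 32 lower with a median of 0.012 (0.71). Relative to the other assays the minor strands lay lower and passed with the deposited scaling (-0.59, adjusted p 0.018) and with scaling on U6 and snoRNA (-0.65, adjusted p 0.0051), which were 0.72 and 0.74 with an estimated correlation, against 0.26 with the deposited scaling without U6 and a range of 0.0051 to 0.995 over their alternatives. Every minor strand assay with a deposited ratio was on card B, and scaling on controls moved the cards by different amounts. With the deposited scaling miR-9, on card A, went from -0.29 to 0.95, and miR-30e*, on card B, from -0.25 to 0.13. The minor strands thus fell below the others with the scale of their card, and these gained calls do not show a strand difference. In each of these lists 0 members passed over all assays and 0 over the list alone. MiR-182 and miR-200c, the 2 tested members of miR-200/miR-183, differed by -0.82 and -0.90, the single tested stem cell member miR-302b differed by 0.016, and 0 of the 8 assays on the Hox-linked list were detected often enough to be tested. The rat-named assay for miR-196c, which that list leaves out and which was looked up after its values were seen, was tested and differed by 1.80 ± 1.48 (SE).

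The 3 most abundant of the 20 neuron assays were far above the mean of the common assays in both groups. Others of the list lay below it, such as miR-124 (-0.88 in CPN and -1.25 in SCPN) and miR-218-2*. MiR-9 stood at 8.30 ± 1.08 in CPN and 8.01 ± 0.68 in SCPN, and miR-9* at 7.13 ± 0.95 and 7.25 ± 0.71, while miR-138 stood at 6.26 ± 0.20 and 7.28 ± 0.13 (SD, n = 3 each), a difference of 1.02 ± 0.52 (SE) with a limma adjusted p of 0.71. The neuron list had 11 members higher and 9 lower, with a median of 0.08 (camera adjusted p 0.53). The 3 activity-linked assays had a median of 1.24 (adjusted p 0.44), with miR-134, itself a 12qF1 member, at 1.24, miR-184 at 1.61 and miR-132 at -0.25. MiR-184 ranged from 0.18 without CPN replicate 1 to 3.50 without CPN replicate 2, and the list, 1.32 above the other assays, from 0.19 to 1.85 without the same samples. In both lists 0 members passed over all assays and 0 over the list alone.

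Markers of other cells did not pass in either direction. Astrocyte assays were lower in 9 of 11 members, with a median of -0.16 (camera adjusted p 0.44), and the 3 oligodendrocyte assays were all lower, with a median of -0.55 (0.44). Microglia and blood assays had 5 of 7 higher with a median of 0.17 (0.92), and vascular assays 3 of 5 higher with a median of 0.08 (0.53). The endothelial miR-126-3p stood at 2.01 ± 0.48 in CPN and 3.12 ± 1.19 in SCPN (SD, n = 3 each). The 2 erythroid assays on the cards gave 0 tested. In these lists 0 members passed over all assays and 0 over the list alone.

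Leaving out 1 sample moved many of these list and assay values by more than 1.5 times. As medians minus those of the other assays, the ranges were -0.70 to -0.15 for miR-34/miR-449 (-0.58 with all samples), -0.78 to -0.30 for miR-15/miR-16 (-0.57), -0.51 to -0.019 for miR-29 (-0.23), -1.13 to -0.37 for miR-99/miR-100/miR-125 (-0.73), -0.26 to -0.019 for the astrocyte list (-0.10), -0.74 to -0.28 for the oligodendrocyte list (-0.49), tested in 2 cases only, and 0.31 to 0.77 for the vascular list, whose values all lay above the 0.19 with all samples. The let-7, neuron, microglia and blood, Sfmbt2 and minor strand lists turned sign in at least 1 case. Among assays the differences ran from 0.46 to 1.59 for miR-126-3p (1.11 with all samples), from 0.71 to 1.61 for miR-134, from -0.52 to -0.036 for miR-132, from -1.35 to -0.19 for miR-182, from -2.71 to 1.22 for miR-200c, from 0.062 to 0.40 for miR-302b, tested in 3 cases only, and from -0.67 to -0.31 for miR-17, and those of miR-9, miR-9* and miR-19b turned sign.

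The small RNA controls were set against the commonly detected microRNAs. On that scale snoRNA135 differed by -1.39 log2 units (SCPN minus CPN) on card A and -0.96 on card B, snoRNA202 by -1.19 and -0.58, U87 by -1.53 and -1.06, Y1 by -1.18 and -0.73, and snoRNA429, on card B alone, by -0.85. U6 differed by -1.14 on card A and 1.18 on card B. The exact permutation p were between 0.1 and 0.9, where 0.1 is the smallest possible, and after adjustment over the 11 tests between 0.55 and 0.90. U6 in CPN replicate 1 had a Ct of 9.91 on card A and 16.2 on card B, against 13.7 on card B in CPN replicate 2 and in CPN replicate 3. The common card B microRNA assays of CPN replicate 1 ran earlier, at a mean Ct of 24.3 against 28.8 and 26.5. The U6 difference of 1.18 on card B thus depends on that sample.

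Scaling on such controls turned a part of the assays from lower to higher in SCPN. Of the 240 ratios in the authors' deposited table, 80.8% lay above 1, with a median of 1.72, against 42.9% of the same assays higher in SCPN in the fit above. Signs were the same in 149 assays (62.1%), and across assays, which are not independent replicates, log2 ratios and fitted differences correlated at Pearson r 0.93 and Spearman rho 0.90. In the authors' deposited table all 35 of the 12qF1 ratios lay above 1, with a median of 6.83 against 1.59 for other assays. Its highest ratios were those of miR-666-5p (35.1), miR-376b* (21.2), miR-770-3p (17.8) and miR-203 (15.1), and miR-133a was at 0.186. Refitted with the deposited scaling, all 306 assays had a median difference of 0.87 in place of -0.08, and 82.0% were higher in SCPN in place of 45.1%. The zero point of the scale is thus not settled, and for assays with small differences the direction is undetermined.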

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

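The scaling on controls, the sample weights, the replicate block, leaving out samples and the limit were planned; the deposited scaling without U6, both samples numbered 1 left out, each card alone and the 12qF1 list at Ct under 30 were chosen after seeing the data. The 12qF1 list kept its direction and its call in all 25 alternatives, with its median 1.52 to 2.15 above the other assays against 1.83 (camera adjusted p 2.31e-23 to 0.00763). Of these, only the alternative with an estimated correlation, at 0.00763, is limited by the number of samples, as the others kept the preset correlation. Trend and robust moderation does not enter camera, so for every list that alternative repeats the reported test. The count at adjusted p 0.05 was 0 in 21 of 22 refits and 1 with sample weights. At a threshold of 0.10 it was 0 as reported, 1 with the deposited scaling, with U6 and snoRNA and with sample weights, 2 with assays detected in all 6 samples, with the deposited scaling without U6 and without CPN replicate 2, and 0 in the other refits. The count at unadjusted p 0.05, 25 as reported, was 42 with sample weights, 51 with the replicate block, 42 with the deposited scaling without U6, 8 on card B alone, where fewer assays were tested, and 14 to 32 with each sample left out. The replicate block changed no other call except the counts over the lists alone given for 12qF1 and miR-181. The share of assays higher in SCPN, 45.1%, was 82.0% with the deposited scaling, 80.7% with U6 and snoRNA and 90.5% with the deposited scaling without U6, as these move every assay by 1 amount per sample and card. The median of all assays then was 0.87, 0.81 and 1.08 in place of -0.08. The miR-17/miR-92 list, at -0.53 relative to the other assays, kept its direction and lost its call in 16 of 24 alternatives: -0.25 with the deposited scaling (adjusted p 0.13), -0.22 with the U6 and snoRNA scaling (adjusted p 0.13), -0.45 with quantile normalization (adjusted p 0.087), -0.46 with a limit of Ct 32 (adjusted p 0.055), -0.50 with no limit and no filter (adjusted p 0.079), -0.45 with assays detected in all 6 samples (adjusted p 0.16), -0.54 with mouse-named assays (adjusted p 0.058), -0.53 with an estimated correlation (adjusted p 0.61), -0.39 with the deposited scaling without U6 (adjusted p 0.13), -0.29 with both samples numbered 1 left out (adjusted p 0.2), -0.42 with card A (adjusted p 0.24) and -0.94 with card B (adjusted p 0.12), and -0.62 to -0.46 with each sample left out. Fewer assays or samples enter the card, mouse-named and left-out settings; the cause was not tested for the rest. The difference in detected assays, -4.67, ranged from -27.7 to 8.50 with each sample left out. MiR-193b kept a difference of 1.598 to 3.23 and miR-365 of 1.65 to 3.23. Of the 94 named assays 49 kept their sign in each alternative in which they were tested and 45 did not, 34 of these under a scaling on controls; the 20 with the smallest p all kept theirs where tested. The count of 12qF1 members past the threshold over the list alone, 1 as reported, ran from 0 to 18, and among added alternatives was 6 with the deposited scaling without U6, 0 without both samples numbered 1 and 3 on card B. Assays near Ct 35 rest on the limit.

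Signs turned under the 3 scalings on controls (log2 differences in the order deposited scaling, U6 and snoRNA, deposited without U6): let-7b at 0.59, 0.59, 0.69, let-7c at 0.46, 0.46, 0.55, let-7e at 1.24, 1.24, 1.33, miR-100 at 0.46, 0.45, 0.55, miR-106a at 0.66, 0.66, 0.76, miR-125a-5p at 0.33, 0.33, 0.43, miR-125b-5p at 0.14, 0.13, 0.23, miR-132 at 0.99, 0.99, 1.08, miR-146a at 0.55, 0.55, 0.65, miR-15b at 0.26, 0.25, 0.35, miR-16 at 0.62, 0.62, 0.72, miR-17 at 0.76, 0.75, 0.85, miR-181c at 0.36, 0.36, 0.45, miR-182 at 0.42, 0.42, 0.52, miR-195 at 0.87, 0.87, 0.97, miR-200c at 0.34, 0.34, 0.44, miR-24 at 1.11, 1.10, 1.20, miR-29a at 0.96, 0.95, 1.05, miR-29c at 1.05, 1.04, 1.14, miR-30a at 0.35, 0.35, 0.44, miR-30b at 0.87, 0.87, 0.97, miR-30c at 0.79, 0.79, 0.88, miR-30d at 0.16, 0.16, 0.25, miR-30e* at 0.13, 0.049, 0.60, miR-32 at 0.77, 0.77, 0.87, miR-338-3p at 0.70, 0.69, 0.79, miR-34b-3p at 0.59, 0.59, 0.69, miR-449a at 1.09, 1.08, 1.18, miR-7a* at 0.35, 0.26, 0.81, and miR-9 at 0.95, 0.95, 1.04. Without U6 alone this also held for miR-26b* at 0.16, miR-34c* at 0.38, miR-449c at 0.084 and miR-467a* at 0.025. As medians minus those of other assays, the deposited scaling turned the astrocyte list to 0.016, the Sfmbt2 group to 0.18 and the minor strands to -0.59 (adjusted p 0.018, a call gained, against 0.72 with an estimated correlation). As medians minus those of other assays, the U6 and snoRNA scaling turned the Sfmbt2 group to 0.19 and the minor strands to -0.65 (adjusted p 0.0051, a call gained, against 0.74 with an estimated correlation). As medians minus those of other assays, the deposited scaling without U6 turned the Sfmbt2 group to 0.18 and the minor strands to -0.32. With median scaling, turned values were -0.10 for miR-145, -0.015 for miR-146b, -0.17 for miR-19b, -0.012 for miR-29b* and -0.17 for miR-302b. With quantile normalization, turned values were 0.15 for let-7e, -0.15 for miR-302b, 0.069 for miR-30b, 0.12 for miR-30c, 0.28 for miR-7a* and 0.20 for miR-9. With a limit of Ct 32, turned values were 0.56 for the Sfmbt2 group, -0.029 for the minor strands, 0.047 for let-7e, 0.037 for miR-17*, 0.42 for miR-182, -0.0088 for miR-29b* and 0.24 for miR-338-3p. With no limit and no filter, turned values were -0.046 for the let-7 list, 0.22 for the Sfmbt2 group, -0.052 for the minor strands, 0.017 for let-7e and -1.63 for miR-302b. With assays detected in all 6 samples, turned values were -0.092 for the minor strands. With values past the limit left missing, turned values were 0.10 for the oligodendrocyte list, 0.048 for the Sfmbt2 group, 0.051 for miR-32, -0.14 for miR-466d-3p and 1.05 for rat-named miR-219-1-3p. With sample weights, turned values were -0.14 for the minor strands, -0.17 for miR-19b, 1.09 for miR-200c, -0.38 for miR-9* and 0.13 for rat-named miR-219-1-3p. Without both samples numbered 1, turned values were 0.061 for the astrocyte list, -0.075 for the minor strands, 0.23 for let-7e, -0.060 for miR-19b, 1.95 for miR-200c, 0.48 for miR-449a and -0.050 for miR-9*. On card A alone, turned values were 0.076 for the Sfmbt2 group. On card B alone, turned values were 0.15 for the miR-99/miR-100/miR-125 list. With each sample left out in turn, the values that turned sign in at least 1 case ranged from -1.98 to 0.82 for U6 on card B, from -0.035 to 3.20 for Y1 on card A, from -0.022 to 2.13 for snoRNA202 on card B, from -0.31 to 0.35 for the let-7 list, from -0.10 to 0.66 for the microglia and blood list, from -0.12 to 0.53 for the neuron list, from -0.59 to 0.33 for the Sfmbt2 group, from -0.20 to 0.30 for the minor strands, from -1.10 to 0.099 for let-7b, from -0.54 to 0.37 for let-7e, from -0.82 to 0.64 for miR-145, from -0.029 to 0.38 for miR-146b, from -0.41 to 0.89 for miR-150, from -0.24 to 0.20 for miR-19b, from -2.71 to 1.22 for miR-200c, from -0.43 to 0.064 for miR-24, from -0.72 to 0.031 for miR-29a, from -0.60 to 0.77 for miR-29b*, from -1.02 to 0.39 for miR-29c, from -0.80 to 0.11 for miR-30b, from -0.76 to 0.22 for miR-30e*, from -1.42 to 0.23 for miR-338-3p, from -0.88 to 0.29 for miR-449a, from -2.83 to 3.24 for miR-466d-3p, from -1.85 to 0.15 for miR-467b*, from -0.77 to 0.56 for miR-7a*, from -0.94 to 0.18 for miR-9, from -0.49 to 0.48 for miR-9* and from -2.47 to 0.19 for rat-named miR-219-1-3p, where the controls are in raw Ct. The calls that the minor strands gained under scaling on controls follow the unequal shift of cards A and B given in the results. For the rest the cause was not tested beyond the shift of the scale itself.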

Other observations

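The tests of the U6 wells and of all assays past the adjusted threshold were chosen after the results were seen. Y1 was added to the reading of the U6 test after its values were seen, which left that test open. The intervals that decide how the tests of position within the cluster, strands and other clusters are read were also set afterwards. Because a p above the threshold does not show that values are alike, those tests are reported here as open, although they had been planned to exclude a difference whenever the p was 0.05 or more.

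Outside the 12qF1 region, 16 other neighbourhoods of 3 or more tested microRNA assays were compared in the same way. The assays from Mir99b to Mir125a, which include let-7e, had a median log2 difference of -0.96 over 5 assays, and those from Mir450b to Mir322 on the X chromosome had -1.18 over 6 assays. The assays from Mir23b to Mir24-1 had a median of 1.08 over 3 assays. None of the 16 passed, and the smallest adjusted p with an estimated correlation was 0.569, so a shift of any of them remains undetermined at this number of samples. Within the Mir379 to Mir410 genes, the median of the assays at lower coordinates minus that of the others was 0.15 (bootstrap interval -0.81 to 0.81, two-sided permutation p 0.652, 29 assays). The 8 assays of the 12qF1 list named with an asterisk had a median 0.19 above that of the other 35 (interval -0.66 to 2.33, one-sided permutation p 0.326). The name does not always mark the less abundant strand. MiR-485* stood at 2.92 in CPN and 3.83 in SCPN, against -8.21 and -4.00 for miR-485. Both intervals are too wide to tell a difference from none, and assays of 1 cluster are not independent.

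The higher level of the 12qF1 microRNAs in SCPN was weighed against technical explanations. The detection limit is argued against, since the 14 members with Ct under 30 in all 6 samples lay 1.57 above other such assays, with 1.43 to 1.85 when each sample was left out. A linear effect of template amount is argued against by the balance of the groups, whose mean Ct differed by 0.246 cycles on card A and 0.187 on card B. The slope on mean Ct within groups predicts a list difference of 0.00123 (-0.029 to 0.082 over samples left out) against 2.01 observed. With groups this balanced even a moderate slope would predict a small difference, so the slope itself adds little. Of the 10 splits of the 6 samples, 1, the real one, gave a list shift as large, at 1.83 against 0.97 for the highest other, and 10 splits are too few for a share under 0.05. What stays open is a chance difference between so few samples, in a cluster the study singled out from them. The neuron class the design names, untested in independent samples, and any difference in sorting between the classes also stay open. A regulated difference of this locus may therefore be offered as a hypothesis only.

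The count of assays at an unadjusted p under 0.05 was 25 in the real split, and 5 of the 10 splits gave as many. The highest other count was 56, in the split that set CPN replicates 1 and 3 and SCPN replicate 1, the samples with the most template, against the rest. The splits that keep both samples numbered 1 on the same side gave 29, 56, 26 and 25, and as these samples share a number and also have the lowest Ct, no test here separates template amount from the pairing. Among the splits that part all 3 pairs the others gave 2, 7 and 4, and with the replicate block 8, 15 and 7 against 51 in the real split. At adjusted p 0.05 the real split gave 0 and so did every other split, so all 10 gave as many, and 10 splits are too few for a share under 0.05.

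U6 in CPN replicate 1 ran late on card B. The gap between cards exceeded the mean of the other 5 samples by 6.52 cycles, whereas snoRNA135, snoRNA202 and U87 exceeded theirs by at most 1.17, which argues against less template on that card. Y1 exceeded its own by 6.17, with a gap of 10.5 cycles in that sample and of 2.86 to 7.81 in the others, so a failure confined to the U6 wells is left open. No cause shared by U6 and Y1 and no biological explanation was tested. The U6 wells enter the deposited scaling of card B, where the median deposited ratio was 1.16 against 2.14 on card A.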
